A study of Homo sapiens with 6 samples.

How the data were processed

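RNA was measured in 6 libraries of human primary melanocytes (HEMn-MP, pigment cells of the skin kept in culture without being an established line). Per the labels, the cells grew as a monolayer, received 100 pmol of siRNA by nucleofection, which carries RNA into cells with an electric pulse, and were then moved into a sphere culture. RNA for total RNA sequencing was taken 24 hours after nucleofection. The labels place 3 libraries in the siScramble group (control siRNA) and 3 in the siSASH1 group (siRNA against SASH1), with replicates numbered 1 to 3 in each. The labels do not say that replicates came from separate cultures or donors, so every p-value measures only the spread between these samples, which may be technical.

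The values are TPM (the transcript share of each gene, scaled by its length), as deposited by the authors in a table of 42257 rows named by gene symbol. Per the submitters' processing notes, cutadapt 3.5, STAR 2.7.8a, RSEM and edgeR were used by the authors with the GRCh38 genome. The notes give these tools no role or order, and the gene annotation was not given in the sources used here. All but 57 rows held values given to 2 decimals (within 1e-06 TPM). Of all rows, 23301 were above 0 in at least 1 library. TPM keeps no sequencing depth, so the depth of each library is unknown, and no counting interval or detection floor was computed. An exact 0 in such a table can be a failed estimate, so a gene without signal is described as listed at 0. TPM is a share of each library, so a change in abundant transcripts moves all others.

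Symbols were matched to RefSeq annotation of GRCh38.p14 for coordinates. Of 42257 rows, 41512 matched by name, as did 13482 of the 13611 tested. Transcript length and GC content came from GENCODE release 29, as medians over each gene's transcripts, and were found for 12722 tested genes (93.5%). The sequences of the 5S genes in that release were compared with that of RNA5S9. Y-linked genes and XIST were tested with the rest and are not reported.

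Values were analysed as log2(TPM + 1) for the 13611 genes with a mean of at least 1 TPM over all 6 libraries. A fold change is therefore on the log2(TPM + 1) scale, which understates the change of low genes. The difference between groups was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, 2-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Intervals are 95% intervals from that fit. For SASH1 and for sums of genes a 2-sided exact permutation test of 3 against 3 libraries was added. It cannot give a p below 0.1, the smallest value possible in this design.

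The gene lists, 39 in number, were fixed before the data were examined, together with the design, the rule for named genes and the other settings tried. They covered the cell cycle, pigmentation, melanocyte identity, adhesion and matrix, signalling outputs, stress, metabolism, translation, reported SASH1 partners, and markers of 5 other cell types. The 36 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, which asks whether members rank above or below the other tested genes. Benjamini-Hochberg adjustment ran over the 36 lists. Camera was repeated with an estimated correlation and with ranks, and fry was run beside it as a test of whether members moved one way on balance. Members passing were counted over all genes tested and adjusted over the list alone.

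Named genes were SASH1, then up to 12 genes per direction that passed the test with non-overlapping groups and a mean of at least 3 TPM, and up to 2 members of each list, taken from those of smallest p. Identifier-only names, small nuclear, small nucleolar and microRNAs, and pseudogenes were left out by the rule, and appear only where a setting changed their call, or as a copy or overlapping gene of a named gene. Since few genes passed, the 10 genes of smallest p in each direction at a mean of at least 3 TPM are also named, a choice made after values were seen. Textbook markers of melanocytes and of mitosis outside this rule were likewise chosen after values were seen.

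Libraries with the same replicate number were checked for shared deviations. Over all tested genes, their deviations from the group means correlated at 0.30, 0.28 and 0.14 for replicates 1, 2 and 3, each above the limit of 0.1 set for pairing, while differently numbered libraries correlated between -0.26 and 0.04. The numbers were therefore taken to pair the samples. The pairing comes from the data and the shared numbers in the labels, not from a stated batch, and a fit with the replicate number as a block was run beside the unpaired one.

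Other settings fixed at the same time were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 TPM, quantile normalization, median centring, TPM rescaled without mitochondrially encoded genes and the 20 most abundant genes, eBayes without the trend, robust eBayes, library weights, the replicate block, a null of at most a 1.2-fold change (treat), and leaving out each library in turn. A correction for GC content and length, by natural splines with 4 degrees of freedom within each library, was added after the data were examined, alone and with the block, as were the estimated correlation with the block and, for the G2/M and mitosis list, fits with the block that left out both libraries of a replicate number. A paired exact sign-flip test of that list was added then too. The steps were tested on simulated data with the means of the 13611 genes and their spreads after eBayes, which draws them towards the mean-variance trend. In 20 draws with 200 changed genes each, 69.3% of genes changed 1.5-fold were recovered, 96% of those changed 2-fold and 99.7% of those changed 3-fold, with 10.3 false calls per draw. A simulated shift of 0.15 in the G2/M and mitosis list was called by camera at the preset correlation in 20 of 20 draws. Simulated genes varied independently of each other, while members of that list had an estimated correlation of 0.547 in the real data. The draws therefore do not show that such a shift would be called there. These simulated libraries varied independently, so they do not carry the shared variation described above. With 200 changed genes per draw the adjusted threshold is also easier to pass than where few genes change. The real data had 2 genes called, so these shares overstate what would be recovered there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.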

Results

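The transcriptome of human primary melanocytes was measured in 6 libraries, 3 after a scrambled control siRNA (siScramble) and 3 after an siRNA against SASH1 (siSASH1), an adaptor protein with SAM and SH3 domains. Cells had been placed in sphere culture, which per the series description favours stem-like cells, and RNA was collected 24 hours after nucleofection. The comparison of siSASH1 with siScramble asks which transcripts differ when SASH1 is lowered, with mitosis and pigmentation as the processes the series is about. Expression is given in TPM, whose sum per library lay between 992166 and 992478, and the sequencing depth is unknown. Gene levels are given as mean ± SD in TPM (n = 3 libraries per group), siScramble before siSASH1. Between 13475 and 13640 genes per library reached 1 TPM. Rank correlations between libraries across all genes, which are not independent replicates, were 0.955 to 0.959 within groups and 0.954 to 0.958 between groups.

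SASH1 itself was lower in every siSASH1 library than in every siScramble library. The gene lies on chromosome 6 from 148193468 to 148552044 (GRCh38). Its level was 60.0 ± 9.03 TPM (SD, n = 3) in siScramble and 25.6 ± 2.65 TPM (SD, n = 3) in siSASH1. The siScramble libraries held 50.17, 67.92 and 61.97 TPM for replicates 1 to 3, and the siSASH1 libraries 24.80, 28.50 and 23.37 TPM. On the log2(TPM + 1) scale SASH1 fell by 1.19 (95% interval -1.47 to -0.92, limma adjusted p = 0.0286), which leaves 43.7% of the control level of TPM + 1 (interval 36.1% to 52.9%). The mean TPM itself was 42.6% of that in siScramble. Within replicate numbers, 49.4%, 42.0% and 37.7% of SASH1 TPM remained. The exact permutation test gave p = 0.1, the smallest value it can give. The adjusted p was 0.159 without siScramble replicate 2, 0.577 without siScramble replicate 3, 0.145 without siSASH1 replicate 1 and 0.155 without siSASH1 replicate 3, while the log2 change of the SASH1 knockdown stayed between -1.32 and -1.1 in all 6 fits that left out 1 library.

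**Figure D1:**
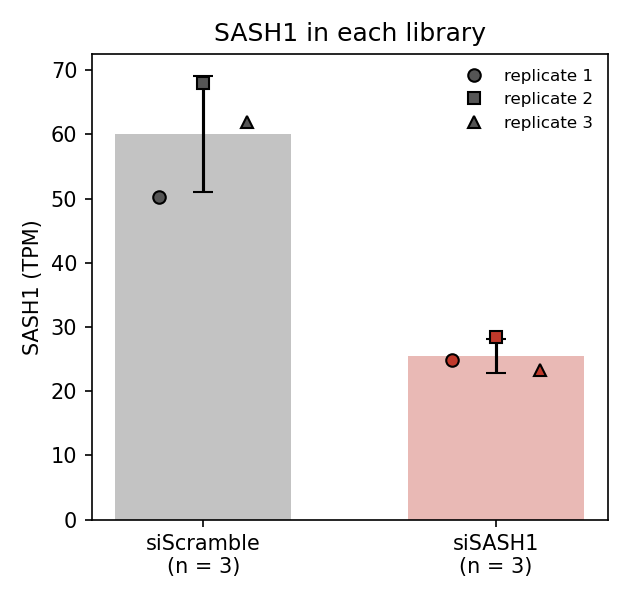
SASH1 expression in TPM (vertical axis) in the siScramble and siSASH1 groups, with bars for the mean, error bars for the SD (n = 3) and a point per library. The siSASH1 libraries sit between 23.37 and 28.50 TPM, all below the siScramble libraries at 50.17 to 67.92 TPM.

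Apart from SASH1, the transcriptome differed little between the groups. Of 13611 genes tested with limma, 2 were lower (SASH1 and the 5S ribosomal RNA gene RNA5S9) and 0 were higher. At an unadjusted p under 0.05 there were 150 genes higher and 59 lower, 209 together where chance gives 681. This count depended on the libraries: it was 177 to 618 in fits that left out 1 library, with the 618 without siSASH1 replicate 1, and 728 with library weights. Groups did not overlap in 749 genes (5.50%, where chance gives 10%). For 13453 genes (98.8%) the 95% interval of the difference lay within 2-fold in either direction on the log2(TPM + 1) scale. The median log2 difference over all tested genes was 0.03. With the replicate number as a block, 3 genes were lower, namely RNA5S9, SASH1 and LOC128092253, with 0 higher and 529 genes at an unadjusted p under 0.05.

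RNA5S9, a 5S ribosomal RNA copy on chromosome 1 (228628146 to 228628266), was listed at 13.92, 27.72 and 19.77 TPM in siScramble replicates 1 to 3 and at 0 in all 3 siSASH1 libraries (limma adjusted p = 9.38e-05). Its transcript is 119 bases long, and 16 other 5S genes differ from it at 1 base, all of them listed at 0 in every library. The table has 520 rows for 5S genes and pseudogenes, of which 6 were above 0 in any library and 0 in every library. Summed over all of them, TPM was 83.26, 27.72 and 42.16 in siScramble and 9.21, 13.28 and 33.49 in siSASH1 (exact permutation p = 0.2), though the other 5S rows above 0 share at most 25 bases in a row with RNA5S9. LOC128092253, which passed only with the block (limma adjusted p = 0.00321), was at 37.49, 20.84 and 9.24 TPM in siScramble and at 4.03, 0 and 0 TPM in siSASH1. It lies inside TBPL1 on chromosome 6, a gene for a TBP-like transcription factor, so their reads can be hard to separate. TBPL1 was at 26.5 ± 2.88 TPM (SD, n = 3) in siScramble and 27.1 ± 3.60 TPM in siSASH1. The sum of TBPL1 and LOC128092253 was 66.84, 44.43 and 35.89 TPM in siScramble and 29.04, 25.03 and 31.25 TPM in siSASH1 (exact permutation p = 0.1), so it was not level between the groups.

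No gene other than SASH1, RNA5S9 and LOC128092253 passed in either fit, and the genes of smallest unadjusted p are given as values only. On the higher side, WEE1, the kinase that holds CDK1 inactive before mitosis, was at 4.00 ± 0.0473 TPM in siScramble and 6.25 ± 0.919 TPM in siSASH1, a log2 difference of 0.53 (95% interval 0.25 to 0.81). The endothelial matrix gene MMRN2 was at 2 ± 0.580 and 4.09 ± 0.526 TPM, and SYCP2 of the meiotic synaptonemal complex at 4.98 ± 1.56 and 8.02 ± 1.19 TPM. The zinc finger gene ZNF346 was at 12.3 ± 1.21 and 16.4 ± 1.01 TPM, the mitochondrial fission gene GDAP1 at 22.7 ± 1.16 and 27.6 ± 1.55 TPM, and the noncoding LINC02482 at 6.59 ± 0.702 and 8.96 ± 0.599 TPM. The other 4 share sequence with neighbours or copies, so their values are uncertain. These were the readthrough transcripts CHKB-CPT1B (5.33 ± 0.652 and 8.55 ± 0.927 TPM) and NDUFC2-KCTD14 (2.62 ± 0.853 and 4.88 ± 0.290 TPM), and the duplicated genes FAM27B (2.22 ± 1.31 and 5.73 ± 1.21 TPM) and FAM156B (8.82 ± 2.61 and 14.04 ± 2.76 TPM). The sum of CHKB-CPT1B, CHKB and CPT1B was 139 ± 5.26 and 146 ± 15.3 TPM (exact permutation p = 0.7). Most of it was CHKB, at 112.9 ± 6.54 and 113.1 ± 11.7 TPM. CPT1B alone was higher in every siSASH1 library, at 20.8 ± 1.05 and 24.3 ± 3.02 TPM (exact permutation p = 0.1). The sum of FAM156A and FAM156B was 22.8 ± 2.07 and 26.2 ± 5.10 TPM (exact permutation p = 0.5 without pairing), and was higher in siSASH1 within each replicate number.

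On the lower side, TLN1, which encodes the focal adhesion protein talin, was at 180.1 ± 4.14 TPM in siScramble and 160.01 ± 1.22 TPM in siSASH1, a log2 difference of -0.17 (95% interval -0.31 to -0.03). The retinoid-responsive gene RARRES1 was at 4.17 ± 0.679 and 2.71 ± 0.312 TPM, and the cofilin phosphatase gene PDXP at 13.9 ± 0.330 and 10.98 ± 1.05 TPM. The ADP-ribose hydrolase gene MACROD1 was at 21.4 ± 1.85 and 17.4 ± 0.950 TPM, and the noncoding LINC02381 at 23.2 ± 0.403 and 18.8 ± 0.322 TPM. The histone gene H4C14 was at 16.9 ± 0.636 and 11.9 ± 3.38 TPM, FBXO16 at 7.28 ± 0.321 and 5.70 ± 0.366 TPM, PLPP4 at 5.35 ± 0.427 and 3.97 ± 0.423 TPM, and CNBD2 at 7.24 ± 0.846 and 5.24 ± 0.937 TPM. The splicing factor gene U2AF1 was at 29.8 ± 16.4 and 9.46 ± 8.59 TPM. U2AF1 has a near-identical copy on the same chromosome (LOC102724594, also called U2AF1L5), and their sum was 77.1 ± 4.201 TPM in siScramble and 77.5 ± 3.34 TPM in siSASH1 (SD, n = 3 each, exact permutation p = 0.9).

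Genes of mitosis lay slightly higher in siSASH1, as a group and not one by one. In the G2/M and mitosis list, 48 of 54 tested members had a positive log2 difference, with a median of 0.13, and the median difference was 0.12, 0.05 and 0.20 within replicate numbers 1 to 3. Camera placed the list above the other tested genes (adjusted p = 0.0043 at the preset correlation), and that call was lost with an adjusted p = 0.792 with an estimated correlation. G2E3, a ubiquitin ligase gene of the G2/M phase, was at 8.22 ± 0.162 TPM in siScramble and 10.2 ± 0.745 TPM in siSASH1, and NUSAP1, a spindle protein gene, at 19.0 ± 5.02 and 24.3 ± 3.30 TPM. Other mitotic genes differed less than their own spread: the cyclin gene CCNB1 was at 40.6 ± 9.80 and 44.9 ± 3.66 TPM, TOP2A at 10.8 ± 4.52 and 12.2 ± 2.71 TPM, the checkpoint kinase gene BUB1 at 6.68 ± 2.45 and 7.54 ± 1.18 TPM, and the proliferation marker MKI67 at 3.64 ± 0.567 and 3.78 ± 1.01 TPM. No member passed over all genes or adjusted over the list alone (0 in limma with and without the block, 1 at an unadjusted p under 0.05), and all 54 intervals lay within 2-fold. Per library, the mean log2(TPM + 1) of the list was 3.559, 3.836 and 3.338 in siScramble and 3.706, 3.861 and 3.545 in siSASH1 (exact permutation p = 0.5 without pairing). Within replicate pairs it was 0.15, 0.03 and 0.21 higher in siSASH1 (paired exact sign-flip p = 0.25, the smallest value possible with 3 pairs). With the replicate block, camera gave an adjusted p = 9.00e-06 at the preset correlation and an adjusted p = 0.587 with an estimated correlation. With both libraries of 1 replicate number left out in that fit, the relative median was between 0.0580 and 0.1502. Camera's adjusted p was at most 0.0289 at the preset correlation and at least 0.705 with an estimated correlation. The list was higher within each pair, so a positive relative median was to be foreseen here. Without siScramble replicate 3, the library with the lowest level, the list's median was -0.01 relative to all genes (camera adjusted p = 0.482). Leaving out siSASH1 replicate 1 or siSASH1 replicate 2 also ended the call (adjusted p = 0.0848 and 0.742), and without siScramble replicate 2 the relative median was 0.20. These fits leave 1 library without its partner, so they also carry differences between replicate numbers.

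Medians of the lists for chromosome segregation, the kinetochore and S phase were above 0, as was the median of all genes at 0.03. Of 22 tested genes for cohesin, condensin and chromosome segregation, 19 had a positive difference (median 0.10), with NCAPG, a condensin subunit gene, at 3.05 ± 1.11 and 4.62 ± 0.201 TPM and the kinesin gene KIF4A at 15.7 ± 1.08 and 17.9 ± 2.14 TPM. Camera called this list at the preset correlation (adjusted p = 0.0365) and on ranks (adjusted p = 0.0174), and the call was lost at an adjusted p = 0.744 with an estimated correlation. It was also lost after correction for GC content and length (median 0.04, adjusted p = 0.144, and 0.0698 with the block). The kinetochore and spindle checkpoint list (29 of 37 positive, median 0.08, adjusted p = 0.129) and the S phase list (29 of 40 positive, median 0.07, adjusted p = 0.178) were not called by camera, and had medians of 0.04 and 0.01 after correction for GC content and length. BUB3 was at 78.8 ± 2.34 and 87.2 ± 4.23 TPM, CENPQ at 5.04 ± 0.187 and 5.89 ± 0.535 TPM, the replication helicase gene MCM4 at 23.1 ± 0.995 and 28.5 ± 3.75 TPM, and CASP8AP2 at 7.37 ± 0.595 and 8.74 ± 0.756 TPM. The S phase list was called without siScramble replicate 2 (adjusted p = 0.0253). Cell cycle inhibitors and p53 targets were not called, with medians of 0.00 and 0.04 and camera adjusted p-values of 0.128 and 0.844. CDKN1C, an inhibitor of cyclin-dependent kinases, was at 196 ± 15.2 and 167 ± 19.6 TPM, RBL2 at 36.9 ± 1.30 and 40.6 ± 3.06 TPM, the DNA repair gene XPC at 37.1 ± 2.51 and 41.2 ± 3.13 TPM, and TP53INP1 at 30.0 ± 1.44 and 33.3 ± 2.996 TPM. The replication-dependent histones were placed below other genes (adjusted p = 0.0175, and 0.655 as adjusted p with an estimated correlation), while their median was -0.04 and their mean 0.00. H2BC11 was at 2.50 ± 0.313 and 1.58 ± 0.432 TPM, and H4C12 was listed at 0 in all 3 siScramble libraries and at 0, 8.55 and 2.61 TPM in siSASH1.

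Pigment genes were among the most abundant transcripts, and 31 of the 32 tested in the melanin synthesis and melanosome list had intervals within 1.5-fold on the log2(TPM + 1) scale. TYRP1, a melanosomal enzyme gene, ranked 10 of 42257 rows by mean TPM at 6202 ± 743 TPM in siScramble and 6168 ± 916 TPM in siSASH1, a log2 difference of -0.01 (95% interval -0.30 to 0.27). PMEL, the melanosome fibril gene, was at 4770 ± 744 and 4767 ± 675 TPM, MLANA at 3170 ± 244 and 3200 ± 505 TPM, DCT at 2474 ± 384 and 2569 ± 336 TPM, and TYR, which encodes tyrosinase, at 2088 ± 144 and 2052 ± 244 TPM. The melanin synthesis and melanosome list of 32 tested genes had a median of 0.01 and a mean of 0.02, beside a median of 0.03 over all genes. Its camera direction was lower (adjusted p = 0.424). HPS3 was at 37.3 ± 1.68 and 40.4 ± 3.94 TPM, and LYST at 190 ± 14.9 and 201 ± 11.8 TPM. Without siScramble replicate 1 this list was called lower (relative median -0.06, adjusted p = 0.0188). Genes of melanosome transport and dendrites had a median of 0.05 (adjusted p = 0.615). RAB17 was at 3.83 ± 0.852 and 4.59 ± 0.196 TPM and CDC42 at 45.5 ± 1.49 and 50.3 ± 5.12 TPM.

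Regulators of melanocyte identity and of the stem-like state were not called either. MITF, the melanocyte master regulator, was at 228.1 ± 33.3 TPM in siScramble and 241.8 ± 35.7 TPM in siSASH1, a log2 difference of 0.08 (95% interval -0.22 to 0.39). SOX10 was at 652.7 ± 18.8 and 644.7 ± 65.7 TPM, and NGFR, a neural crest marker, at 107.1 ± 19.7 and 105.2 ± 21.3 TPM. The melanocyte lineage regulators had a median of -0.01 and a mean of 0.00 (camera adjusted p = 0.323). ERBB3 was at 376 ± 16.9 and 400 ± 4.02 TPM and SOX6 at 17.8 ± 1.84 and 19.0 ± 2.76 TPM. The neural crest and melanocyte stem cell list had a median of 0.04 with the camera direction lower (adjusted p = 0.947). ZEB2 was at 173 ± 13.2 and 184 ± 11.3 TPM and ABCB5 at 127 ± 25.1 and 143 ± 30.0 TPM. All 16 intervals of the lineage list and all 18 of the stem cell list lay within 1.5-fold on the log2(TPM + 1) scale, which understates the change of low genes.

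Over the gene lists as a whole, camera at the preset correlation called 13 of 36, with 2 above the other genes (both of mitosis, described before) and 11 below. With an estimated correlation 0 lists were called (adjusted p from 0.655 to 0.977, 2 lists at an unadjusted p under 0.05), and fry called 0 as well (adjusted p of at least 0.99, 0 lists at an unadjusted p under 0.05, and 3 with the block, 0 called). Of 888 tested list members, 0 passed in limma over all genes or adjusted over the list alone, with 9 at an unadjusted p under 0.05 (45 with the replicate block, 0 passing), and 879 had intervals within 2-fold. Of the 13 calls, 0 were kept in all 6 fits that left out 1 library. The ribosomal proteins and extracellular matrix lists kept theirs in 5 of 6, the ATF4, actin and cholesterol lists in 4, the G2/M, interferon and histone lists in 3, the cohesin, immediate early, oxidative phosphorylation and TGF-beta lists in 2, and the autophagy list in 1.

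The lists below the other genes differed by small amounts. Interferon response genes had a median of -0.09 (34 of 47 negative, preset adjusted p = 1.96e-05, adjusted p = 0.722 with an estimated correlation). Within replicate numbers 1 to 3 the median, not taken relative to all genes, was 0.01, -0.05 and -0.18. Without siSASH1 replicate 2 the median relative to all genes was -0.0247 (camera adjusted p = 0.587). IRF1 was at 6.32 ± 2.08 and 4.33 ± 0.343 TPM and PSMB9 at 24.8 ± 2.20 and 21.7 ± 0.700 TPM. Cholesterol synthesis genes had a median of -0.04 (21 of 27 negative, preset adjusted p = 7.64e-04, adjusted p = 0.744 with an estimated correlation). INSIG1 was at 33.2 ± 4.73 and 29.1 ± 2.39 TPM. Extracellular matrix genes had a median of -0.05 (25 of 33 negative, preset adjusted p = 9.78e-04, adjusted p = 0.655 with an estimated correlation). TIMP1 was at 346 ± 19.0 and 317 ± 33.0 TPM and COL5A2 at 93.6 ± 6.64 and 101 ± 6.81 TPM. The ribosomal proteins list had a median of -0.02 (58 of 76 negative), or -0.0519 relative to all genes. After quantile normalization its relative median was 0.00365 (camera adjusted p = 0.974). Within replicate numbers 1 to 3 its median, not taken relative to all genes, was -0.12, 0.04 and 0.02, so it was negative only in replicate 1. The list was called at the preset correlation (adjusted p = 1.63e-06) and on ranks (adjusted p = 5.58e-08), and the call was lost at an adjusted p = 0.744 with an estimated correlation. RPL28 was at 1162 ± 56.0 and 1073 ± 46.2 TPM.

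**Figure D2:**
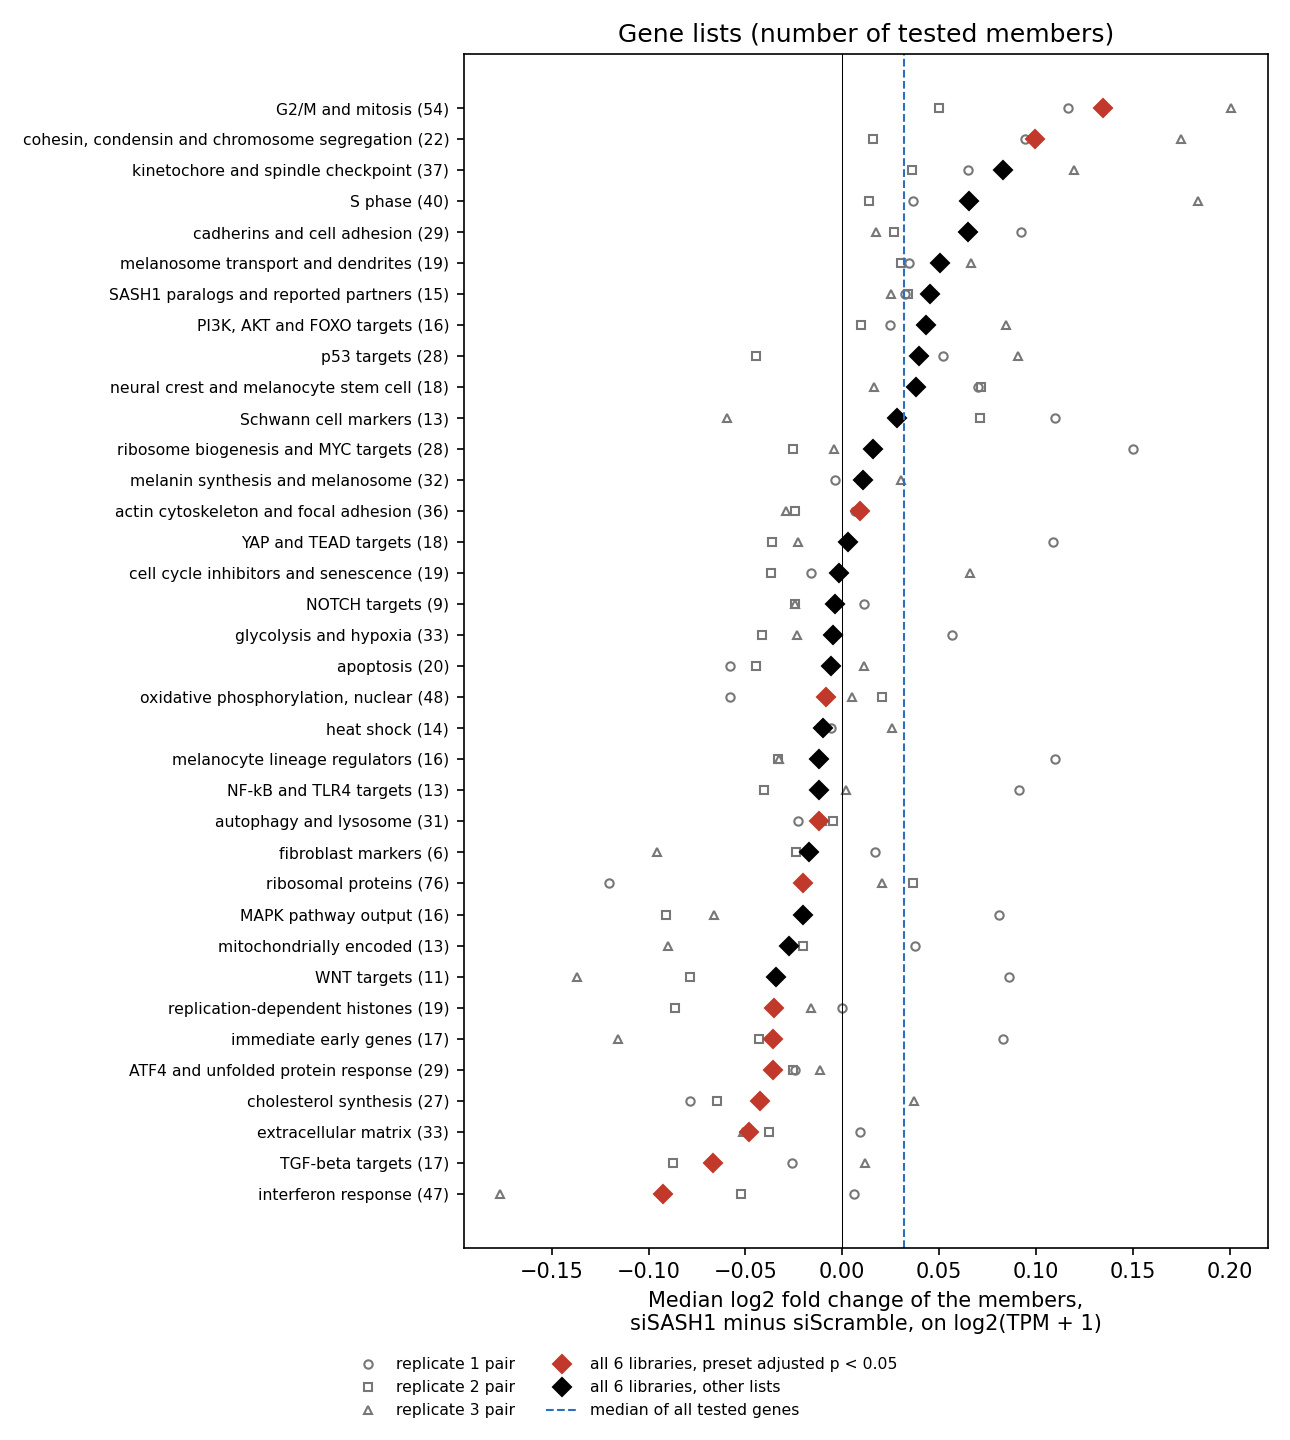
Median log2 fold change of each list's members (horizontal axis, siSASH1 minus siScramble on log2(TPM + 1)) for the 36 tested lists (vertical axis, tested members in brackets), with diamonds for all 6 libraries (red where camera called the list at the preset correlation), open symbols for the replicate pairs and a dashed line for the median of all genes. The G2/M and mitosis list lies highest at 0.13 and interferon response lowest at -0.09, while the ribosomal proteins list lies at -0.02. Relative to the median of all genes, the ribosomal proteins list moved from -0.0519 to 0.00365 after quantile normalization.

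Genes of stress responses, cell shape and housekeeping made up most of the other lists that camera placed below the rest at the preset correlation. ATF4 and unfolded protein response genes had a median of -0.04 (preset adjusted p = 0.0124, adjusted p = 0.744 with an estimated correlation, adjusted p = 0.646 without siScramble replicate 3). CRELD2 was at 75.7 ± 4.96 and 67.2 ± 7.88 TPM and MTHFD2 at 6.86 ± 0.715 and 5.87 ± 0.370 TPM. Actin cytoskeleton and focal adhesion genes had a median of 0.01, a mean of -0.02 and a camera direction lower (preset adjusted p = 0.0138, adjusted p = 0.722 with an estimated correlation). FLNA, which encodes filamin A, was at 484 ± 52.6 and 425 ± 14.01 TPM beside TLN1. Immediate early genes had a median of -0.04 (preset adjusted p = 0.0175, adjusted p = 0.722 with an estimated correlation, adjusted p = 0.144 after GC and length correction). JUND was at 32.2 ± 3.35 and 27.5 ± 3.04 TPM and JUNB at 13.4 ± 1.87 and 12.5 ± 1.01 TPM. Nuclear genes of oxidative phosphorylation had a median of -0.01 (preset adjusted p = 0.0411, adjusted p = 0.792 with an estimated correlation). NDUFS1 was at 72.0 ± 5.86 and 78.6 ± 0.965 TPM and COX6A1 at 549 ± 15.9 and 517 ± 18.4 TPM. TGF-beta targets had a median of -0.07 (preset adjusted p = 0.0442, adjusted p = 0.722 with an estimated correlation, adjusted p = 0.245 after GC and length correction). ID3 was at 15.1 ± 3.49 and 11.8 ± 5.002 TPM and SKIL at 8.30 ± 1.40 and 9.39 ± 1.01 TPM. Autophagy and lysosome genes had a median of -0.01 (preset adjusted p = 0.0456, adjusted p = 0.744 with an estimated correlation). CTSD was at 2271 ± 111 and 2078 ± 147 TPM and ATP6V1A at 86.1 ± 9.23 and 92.7 ± 6.29 TPM.

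The list of reported SASH1 partners and the lists of signalling targets and adhesion given here were not called by camera. The actin cytoskeleton and focal adhesion list, described before, shares CRKL, CTTN and LASP1 with the partner list. It was called lower at the preset correlation only (camera adjusted p = 0.0138, and 0.722 with an estimated correlation). The list of SASH1 paralogs and reported partners had a median of 0.05 with 13 of 15 tested genes positive (camera adjusted p = 0.738, and 0.432 as adjusted p by fry with the block). TRAF6 was at 8.38 ± 0.285 and 9.91 ± 1.11 TPM and TAB1 at 30.1 ± 1.48 and 28.1 ± 1.06 TPM. NF-kB and TLR4 targets, of which 13 of 25 reached the tested level, had a median of -0.01 (adjusted p = 0.189). RELB was at 7.86 ± 1.24 and 5.99 ± 0.842 TPM and NFKBIE at 9.82 ± 1.08 and 11.7 ± 1.24 TPM. Cadherins and adhesion genes had a median of 0.07 (adjusted p = 0.474). ALCAM was at 160 ± 7.79 and 179 ± 9.04 TPM and CADM1 at 74.0 ± 3.26 and 80.1 ± 3.03 TPM. Targets of PI3K, AKT and FOXO had a median of 0.04 (adjusted p = 0.718), and MAPK pathway output a median of -0.02 (adjusted p = 0.206). YAP and TEAD targets had a median of 0.00 with the camera direction lower (adjusted p = 0.544), WNT targets a median of -0.03 (adjusted p = 0.178) and NOTCH targets a median of 0.00 (adjusted p = 0.349). Among them FBXO32 was at 45.7 ± 5.78 and 50.1 ± 5.04 TPM, MAFF at 4.84 ± 0.744 and 4.02 ± 0.923 TPM and ETV1 at 28.3 ± 2.44 and 31.1 ± 4.47 TPM. TEAD1 was at 71.1 ± 9.68 and 79.0 ± 9.70 TPM and AJUBA at 3.75 ± 0.336 and 4.18 ± 0.382 TPM. DKK1 was at 1.87 ± 0.510 and 2.60 ± 0.734 TPM, NKD1 at 1.203 ± 0.121 and 0.973 ± 0.462 TPM and JAG2 at 3.01 ± 0.567 and 3.53 ± 0.852 TPM. HES4 was at 1.15 ± 0.306 and 0.933 ± 0.397 TPM.

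Genes of apoptosis, glycolysis, heat shock and ribosome biogenesis and the mitochondrial genome were not called in the uncorrected, unpaired fit. The apoptosis list had a median of -0.01 (camera adjusted p = 0.0621). After correction for GC content and length it was called lower at the preset correlation (adjusted p = 0.0491, and 0.024 with the block), with an adjusted p = 0.736 with an estimated correlation and the block. BIK was at 2.81 ± 1.02 and 2.13 ± 0.415 TPM. Glycolysis and hypoxia genes had a median of 0.00 (adjusted p = 0.0973). ANKRD37 was at 10.01 ± 1.36 and 8.83 ± 0.315 TPM and MXI1 at 218 ± 3.19 and 234 ± 17.9 TPM. Heat shock genes had a median of -0.01 and a mean of 0.00 (adjusted p = 0.217). HSPB1 was at 1119 ± 117 and 1030 ± 63.8 TPM and HSP90AA1 at 753 ± 102 and 802 ± 57.5 TPM. Ribosome biogenesis and MYC targets had a median of 0.02 with the camera direction lower (adjusted p = 0.947). GNL3 was at 36.8 ± 2.67 and 42.1 ± 3.15 TPM and WDR12 at 63.1 ± 2.01 and 68.8 ± 5.56 TPM. The mitochondrially encoded list had a median of -0.03 (adjusted p = 0.103). MT-ND3 was at 4800 ± 586 and 4354 ± 196 TPM and MT-ND2 at 4110 ± 552 and 3936 ± 646 TPM. The mitochondrially encoded list was called lower with the replicate block at the preset correlation (adjusted p = 0.0268), a call lost at an adjusted p = 0.640 with an estimated correlation and at 0.0698 after correction for GC content and length. Mitochondrially encoded genes made up 11.45%, 8.26% and 9.59% of TPM in siScramble and 11.75%, 8.24% and 9.21% in siSASH1.

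Markers of other cell types were mostly below the level tested. Of 27 keratinocyte markers 4 reached the tested level. CDH3 was at 91.3 ± 16.5 and 81.9 ± 8.80 TPM and KRT10 at 14.6 ± 0.416 and 13.2 ± 0.318 TPM. Of 10 endothelial markers only KDR did, at 3.79 ± 0.765 and 3.52 ± 0.639 TPM, and of 16 immune markers 3 did. CD68 was at 222 ± 30.0 and 206 ± 18.9 TPM and CD14 at 3.47 ± 1.54 and 3.73 ± 1.79 TPM. These 3 lists had too few members for camera and had medians of -0.14, -0.08 and -0.01. The 6 tested fibroblast markers had a median of -0.02 (adjusted p = 0.405). COL1A2 was at 410 ± 9.64 and 397 ± 14.5 TPM, FBLN1 at 32.6 ± 3.57 and 30.1 ± 4.76 TPM and THY1 at 14.7 ± 0.300 and 15.7 ± 0.903 TPM. Schwann cell markers, which share genes with melanocytes, had a median of 0.03 with the camera direction lower (adjusted p = 0.912).

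The libraries differed in how expression followed GC content. Across 12722 genes, which are not independent replicates, the Spearman correlation of each library's deviation with GC content was 0.22, -0.15 and 0.22 in siScramble and 0.43, -0.30 and -0.51 in siSASH1, and the difference between groups correlated at -0.28. The first principal component held 33.1% of the variance, and placed siScramble and siSASH1 replicate 1 on one side and both libraries of replicate 2, with siSASH1 replicate 3, on the other, with siScramble replicate 3 near the middle. After correction for GC content and length, limma called the same 2 genes, with 215 of 12722 at an unadjusted p under 0.05.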

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

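The SASH1 knockdown kept its direction under every setting, and its adjusted p was above the threshold at a log2 change of -1.19 with no filter on low TPM (0.389), with eBayes without the trend (0.157) and with treat (0.11). Leaving out 1 library gave -1.32 to -1.1, with the call lost without siScramble replicate 2 or 3 and without siSASH1 replicate 1 or 3, where fewer libraries remain. The number of genes changed by SASH1 siRNA was 1 under these same settings (no filter, no trend, treat) and 1 to 4 when 1 library was left out. The genes added there were small nucleolar RNAs, SNORA40 without siScramble replicate 1, SNORA5A and SNORA2C without siSASH1 replicate 2, and SNORA47 and SNORA12 without siSASH1 replicate 3.

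The G2/M and mitosis list, at a median of 0.103 above all genes, was called with the preset correlation under every scaling and lost the call with an estimated correlation (adjusted p = 0.792), with fry (adjusted p = 0.99) and with an estimated correlation and the replicate block (adjusted p = 0.587). Without 1 library its median went from -0.0124 (without siScramble replicate 3) to 0.204. The S phase list was called with library weights (0.0401, adjusted p = 0.0433), and ran from -0.0128 to 0.0565 without 1 library. The melanin synthesis and melanosome list ran from -0.0596 to 0.0417. The number of gene lists called, 13, was 6 with no filter, 4 after quantile normalization, 0 with an estimated correlation, 0 with fry, 0 with an estimated correlation and the block, and 6 to 13 without 1 library. Camera's direction turned, without a call, for the ribosomal proteins list after quantile normalization (0.00365) and without siSASH1 replicate 1 (-0.00135, range -0.0829 to -0.00135), for the oxidative phosphorylation, nuclear list with library weights (-0.00141) and for the cholesterol synthesis list without siScramble replicate 1 (0.00938, range -0.139 to 0.00938). Except where given, the cause was not tested. Of the other results and settings, 2494 stayed on the same side of the threshold (52 of these turned sign without a call), 102 lost a call and 17 gained one. The 17 include the number of genes higher, a count that rose from 0 to 2 without siSASH1 replicate 2 and without siSASH1 replicate 3. The correction for GC content and length ended the calls of the immediate early genes and the cohesin, condensin and chromosome segregation list, with and without the block, that of the TGF-beta targets without it and that of the mitochondrially encoded list with it, and the apoptosis list gained one in both fits. The histone list was not tested after it, since 0 of its 19 tested genes were matched to a GC content. Without that correction, the replicate block changed the call of LOC128092253 and of the mitochondrially encoded list and no other call. Keratinocyte, endothelial and immune cell markers had under 5 tested members and were tested in no setting. The depth of the libraries is unknown, so what it limits could not be computed.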

Other observations

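The explanations in this part and their tests were chosen only after results were seen, while the replicate block they use was among the settings fixed earlier. The first pattern weighed is the higher G2/M and mitosis list in siSASH1. A bias by GC content or gene length was tested because the difference between groups correlated with GC content at -0.28. After the correction, in the fit with the replicate block, the median of the list lay 0.0855 above that of all genes (camera adjusted p = 2.4e-05 at the preset correlation, adjusted p = 0.669 with an estimated correlation). Within replicate pairs it was 0.10, 0.04 and 0.12 (mean 0.0868, SE 0.0237) after correction against 0.06, 0.05 and 0.16 (mean 0.0899, SE 0.0330) before it. The correction therefore changed the mean over pairs little. The shift rests on 3 pairs and was not called with an estimated correlation, so this does not decide its cause. A difference in cell cycle stage between the cultures, from SASH1 or from handling, could give the same values and was not tested.

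The 6 libraries can be split into 3 and 3 in 10 ways with the real one counted, too few for a share under 0.05. Counting the real split, 6 moved the G2/M and mitosis list as far as the real one (0.103, highest other 0.281), 5 the S phase list (0.0336, highest other 0.0934) and 7 the melanin list (0.0211, highest other 0.104). In the 3 other splits that part every replicate pair, as the real one does, the values were 0.0113 to 0.0720, 0.0361 to 0.0480 and 0.0034 to 0.0275. The remaining splits keep pairs together and so carry what same-numbered libraries share. For the number of lists called, 1 split, the real one, reached 13 (highest other 12, and 1 to 4 in the 3 splits that part every pair), and for genes called 2 splits, with the real one, reached 2 (highest other 4, and 0 to 1). The split that put siScramble replicates 1 and 3 with siSASH1 replicate 1 had 2429 genes at an unadjusted p under 0.05 against 209 in the real one. Those are the 3 libraries in which expression correlated positively with GC content, so the split shows structure among samples that does not simply follow the siRNA. That structure is not apart from the siRNA either, since the difference between groups correlated with GC content at -0.28.

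The next pattern weighed is that fewer genes had a small p-value than chance gives (209 against 681). Variation shared by libraries of the same replicate number would widen the spread within groups in the unpaired fit. With the replicate block, 529 genes were at an unadjusted p under 0.05, nearer the number chance gives, as this explanation needs. The pairing was itself taken from these genes, so a rise could be foreseen and is no separate evidence. Without the block, library weights gave 728 genes and the fit without siSASH1 replicate 1 gave 618, while the other fits without 1 library gave 177 to 327. No biological explanation was tested.

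The last pattern weighed is RNA5S9 listed at 0 after SASH1 siRNA. Of 67 transcripts of 100 to 150 bases above 0 in any library, 95.5% were listed at 0 in at least 1 library. Among the 49 of these with a mean of at least 1 TPM it was 46, against 0.0481% of genes of at least 1000 bases at that mean, so an estimate of 0 is common at this length. A 0 in at least 1 library is a looser pattern than that of RNA5S9. Of the 67, 5 were above 0 in exactly 3 libraries, and RNA5S9 was the 1 among these that followed the groups. Whether its reads were assigned to other 5S copies cannot be told, since the 29 5S rows sharing at least 50 bases in a row with it were listed at 0 in all 6 libraries, and their sum with RNA5S9 (0 in siSASH1) only repeats RNA5S9. Reads that match several copies may also have been dropped before the table was made, and a loss of 5S RNA caused by lower SASH1 stays open. RNA5SP452, a 5S pseudogene also of 119 bases, was listed at the same 13.92 TPM as RNA5S9 in siScramble replicate 1. TPM is scaled by length, so both values may rest on the same number of reads, and how few cannot be told without the depth.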
